A study of Homo sapiens with 18 samples.

How the data were processed

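RNA sequencing was analysed from 18 libraries of the glioblastoma lines LN229, T98G and U118-MG, with 3 libraries each for the control guide and the DDA1 guide in every line. Per the labels' protocols, cells were grown in DMEM with 10% fetal bovine serum, total RNA was extracted with Trizol and libraries followed a standard Illumina protocol. Whether the libraries are stranded and whether poly(A) RNA was selected is not given in the sources used here. Per the submitters' processing notes, reads were trimmed with fastp 0.19.6, aligned with STAR 2.4.0 to GRCh38 and counted with HTSeq 0.12.4, and DESeq2 is named without a version or a role.

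The deposited gene table holds raw counts for 46218 gene IDs, and the deposited FPKM values equal the count divided by gene length and by the total count, with a single length per gene. The same counts and FPKM values stand in a second deposited table, with 0 differing cells. The authors' deposited table of differential genes holds, per the file headers, a mean normalized read count per group as its signal, a log2 fold change, a p-value and an adjusted p-value, and FPKM values, with columns that name the LN229 groups only. Deposited coordinates of a principal component analysis carry no sample names and were not used here, and neither were gene cluster numbers whose making is not stated. No count line lacked a gene, and 0 data columns were left without a sample. Of the gene IDs 14105 have no symbol in the deposited table, and 44443 were found in GENCODE 29, which gave chromosome and gene type.

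Library totals were 44.9 to 55.1 M, and 94.1 M in LN229 sgCon 1. A floor of 3 counts equals 0.0319 to 0.0668 CPM of unscaled totals. Folds against groups with 0 counts use a floor of 0.0809 CPM, the same 3 counts after TMM scaling in the U118-MG sgDDA1 library where it is highest. Both floors and intervals cover counting error only, since the labels mention no molecular identifiers and PCR copies may be counted. Even counts made up 57.4% to 63.7% of counts from 1 to 19 in every library, for which the sources used here give no reason, so a setting with halved counts was tried. Between replicates of a group the chi-square per gene was 3.99 to 6.89 in LN229 and T98G, and 3.7 to 174.14 in the groups labelled U118-MG.

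Own computations began from the deposited counts, in R 4.3.3. Genes were kept with filterByExpr by the 6 groups, which left 24418, and were scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16. A fit of 6 group means over all 18 libraries gave the contrast of guides in each line, the line by guide interaction with 2 degrees of freedom, and pairwise differences of response. A fit with an additive cell line term gave the contrast across lines. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors (SE) belong to the log2 fold changes, and levels are TMM-scaled CPM as mean ± SD of 3 libraries. All comparisons used the labels as given, including those of the libraries labelled U118-MG, whose control group resembles LN229.

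Gene lists were written before any expression value was seen, 36 in number, and all had at least 5 measured members. They were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Counts of members are given over all genes and adjusted over the list alone. Shared calls between lines were tested with Fisher's exact test. DESeq2 1.42.0 was used as an alternative test and for the comparison with the authors' deposited table.

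Genes named were chosen by a rule set before any expression value was seen. DDA1 came first, then in each comparison the 6 largest rises and 6 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 CPM and all 3 libraries of one group above all 3 of the other, and up to 3 members of each list called. For the comparison across lines this separation was asked in at least 2 lines with the same sign in all 3. The study's own lists were treated the same way whether called or not. The rule asked for protein-coding genes where the files give a gene type and for any gene with a symbol otherwise. The deposited files give none, and the type from GENCODE 29 was used all the same, which departs from that wording. Genes on the Y chromosome were left out of the named genes. Some genes that the rule picks are not reported here. The genes in the first part of the other observations were chosen after their values were seen.

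The procedure was tested on simulated data with 50 changed genes per fold among genes with a mean of at least 50 counts, drawn from the control levels of each line and the estimated spread. The changes were put into T98G alone for T98G and the interaction, and into all 3 lines for the comparison across lines. At 1.5, 2, 4 and 8-fold it recovered 58%, 88%, 98% and 100% in T98G, with 8 of 23193 unchanged genes called. Across lines it recovered 96% at 1.5-fold and 100% above, with 13 of 23179 unchanged genes called. Each changed gene had the same fold in all 3 lines there, whereas the real response differed among the lines for 16728 genes. The rates across lines therefore hold for a shared response only. For the interaction it recovered 22%, 80%, 92% and 100%, with 11 of 23193 unchanged genes called. A list raised in the simulation was called and 0 of 30 random lists were. The simulated counts held no correlation between the genes of a list. The result for lists therefore cannot tell whether the preset correlation suits the real data.

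Alternatives tried were DESeq2, DESeq2 size factors, a robust prior, no filter, a filter of 5 CPM in 3 libraries, a minimum of 2-fold, each line alone, no cell line term, the mean of the per-line contrasts, a replicate block, fry in place of camera and leaving out each library. Added after the data were seen were the fits without the 6 libraries labelled U118-MG, the halved counts, the numbers of genes and lists that differ between T98G and LN229, and the levels of the libraries labelled U118-MG sgCon with a share of 3.37% of U118-MG sgDDA1 taken out. Replicate numbers are not said to pair the libraries, so no block was used in the reported fits.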

Results

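The series measured gene expression by RNA sequencing in LN229, T98G and U118-MG, 3 established human glioblastoma cell lines, each carrying either a control CRISPR guide (sgCon) or a guide against DDA1 (sgDDA1). DDA1 is a small protein that binds DDB1 in the CRL4 ubiquitin ligases, and the title of the series places its phosphorylation by mTORC1 in DNA repair and glioblastoma progression. There were 3 libraries in each of the 6 groups, 18 in all. The deposited gene counts summed to 44.9 to 55.1 M per library, apart from LN229 sgCon 1 with 94.1 M. A floor of 3 counts corresponded to 0.0319 to 0.0668 CPM (counts scaled to library size), and such floors cover counting error only. Between 28292 and 33526 genes had a count above 0, and the 10 most abundant genes took 5.1% to 8.9% of the counts. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

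DDA1 itself (ENSG00000130311, GRCh38 chromosome 19, 17309518 to 17323301, plus strand) was examined in every library first. In LN229 it fell from 48.6 ± 0.829 CPM in sgCon to 33.7 ± 1.40 CPM in sgDDA1 (mean ± SD, n = 3 each), a log2 fold change of -0.53 (SE 0.10, edgeR adjusted p = 0.000642), and all 3 sgDDA1 libraries lay below all 3 controls. In T98G the level was 65.6 ± 3.68 CPM in sgCon and 57.3 ± 2.20 CPM in sgDDA1, with a log2 fold change of -0.20 (SE 0.10) that did not pass the test (adjusted p = 0.197). All 3 T98G sgDDA1 libraries were below all 3 controls, and without the 6 libraries labelled U118-MG the same difference passed (adjusted p = 0.00107). In the libraries labelled U118-MG the control values were 71.8, 56.0 and 50.1 CPM and the sgDDA1 mean was 63.0 ± 3.72 CPM, a log2 fold change of 0.09 (SE 0.10, adjusted p = 0.45). Without the library labelled U118-MG sgCon 1 this difference became 0.25 (adjusted p = 0.0011), and without U118-MG sgCon 3 it was -0.02 (adjusted p = 0.853). The control libraries of this pair resemble LN229, so the difference does not bear on the guide. The response in T98G differed from that in LN229 by 0.33 (SE 0.15), which did not pass the test of the difference (adjusted p = 0.132). A guide that disrupts a coding sequence need not lower the transcript, and DDA1 protein was not analysed here.

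**Figure D1:**
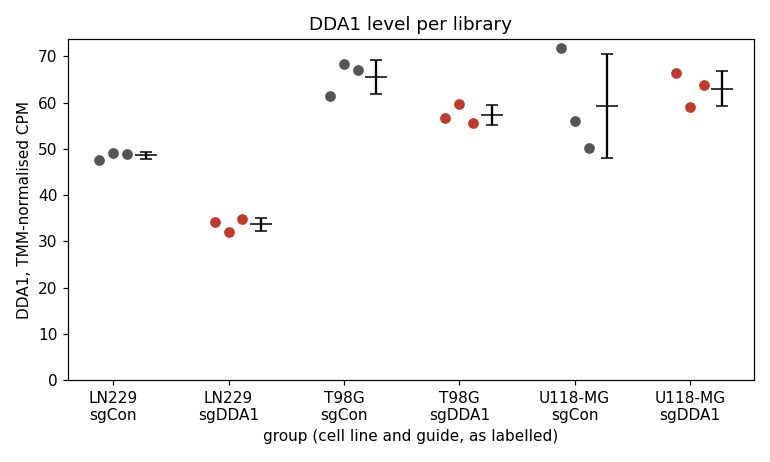
DDA1 level in CPM (vertical axis) in each of the 18 libraries by line and guide, with points for libraries and bars for the mean and SD of 3 libraries. The LN229 sgDDA1 libraries sit between 32.1 and 34.8 CPM against 47.6 to 49.2 CPM in their controls, while the groups labelled U118-MG overlap.

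The first comparison set sgDDA1 against sgCon in LN229. ANKRD1, a cardiac ankyrin repeat protein known as a YAP target, dropped from 61.9 ± 1.70 to 3.03 ± 0.544 CPM (log2 fold change -4.35, SE 0.20, adjusted p = 4.27e-11, n = 3 per group). Among the largest rises were CACNA1I, a T-type calcium channel (0.241 ± 0.0648 to 3.74 ± 0.466 CPM; 3.92, SE 0.31), the helix-loop-helix gene HES2 (3.53, SE 0.35), the fucosyltransferase FUT1 (3.46, SE 0.34), USH1G (3.35, SE 0.27), the homeobox gene DLX3 (3.34, SE 0.37) and the potassium channel KCNJ4 (3.20, SE 0.41). Among the largest falls after ANKRD1 were CASS4 (-1.96, SE 0.44), the axonemal dyneins DNAH17 (-1.95, SE 0.14) and DNAH12 (-1.77, SE 0.30), FAM71F2 (-1.95, SE 0.20) and MGAM (-1.65, SE 0.24). The intermediate filament gene NES, a neural progenitor marker, rose from 9.97 ± 0.549 to 57.0 ± 4.46 CPM (2.52, SE 0.12, adjusted p = 4.27e-11). Several of these genes differed about as much in libraries labelled with the control guide. In U118-MG sgCon 2 and 3 as labelled, against LN229 sgCon 2 and 3, ANKRD1 lay at -3.32, NES at 2.69, CACNA1I at 3.92, HES2 at 3.52, USH1G at 3.37, DLX3 at 3.37, KCNJ4 at 1.93 and FUT1 at 0.71. The LN229 response against sgCon 1 was -4.27, 2.55, 3.36, 3.43, 3.00, 3.04, 2.77 and 2.69 for the same genes. DDA1 lay at 0.11 in the first of these comparisons and at -0.50 in the second, and which guide those libraries received was not tested. If their guide label is right, these changes cannot be assigned to the guide alone. In total 4694 genes were higher and 2491 lower of 24418 tested with edgeR, and at 2-fold or more 2252 were higher and 256 lower. Most of these larger rises were in genes of low abundance, with 952 of 5219 genes at 1 to 10 CPM higher by 2-fold and 3 of 1985 genes over 100 CPM. The count of 7185 called genes became 10898 without the library labelled U118-MG sgCon 1 and 11632 without all 6 libraries labelled U118-MG.

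The list of mTORC1 and ATF4 amino acid genes, called amino acid and mTORC1 genes below, rose in LN229, and the activity of ATF4 or mTORC1 was not tested. Of 30 measured, 23 rose and 1 fell (24 and 1 adjusted over the list alone). The median log2 fold change was 0.68 (camera adjusted p = 7.74e-11; adjusted p = 0.0913 with an estimated correlation). PCK2, a mitochondrial gluconeogenic enzyme, rose from 14.1 ± 0.862 to 76.4 ± 4.24 CPM (2.44, SE 0.14). DDIT4, an inhibitor of mTORC1, rose from 31.3 ± 1.42 to 137 ± 2.94 CPM (2.13, SE 0.16), and the stress gene NUPR1 rose by 3.20 (SE 0.26) from a low level. The same list lay at a median of 0.41 above LN229 sgCon 2 and 3 in the libraries labelled U118-MG sgCon 2 and 3. Genes of the unfolded protein response and chaperones moved the other way, with 2 higher and 21 lower of 27 (3 and 21 adjusted over the list alone). Their median was -0.46 and the adjusted p 2.49e-09 (adjusted p = 0.0486 with an estimated correlation). The constitutive chaperone HSPA8 dropped from 2200 ± 71.6 to 1090 ± 32.6 CPM (-1.02, SE 0.08). HSPA1B (-1.15, SE 0.10) and HSPA1A (-1.59, SE 0.15) were also lower, although these near-identical copies share reads and their separate values are uncertain. In the libraries labelled U118-MG sgCon 2 and 3 the chaperone list lay at -0.15 relative to LN229 sgCon 2 and 3.

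Cell cycle genes were lower in LN229 sgDDA1. Of 35 genes of G2/M and mitosis 13 fell and 0 rose (16 and 1 adjusted over the list alone; median -0.36; adjusted p = 6.7e-06, and adjusted p = 0.336 with an estimated correlation). They included CCNA2 (-0.63, SE 0.10), CDC20 (-0.75, SE 0.14) and AURKA (-0.55, SE 0.10). Of 41 genes of replication licensing and S phase 13 fell and 0 rose, also when adjusted over the list alone (adjusted p = 0.00047; adjusted p = 0.62 with an estimated correlation). Examples were CDC6 (-0.43, SE 0.07), GINS2 (-0.46, SE 0.12) and TYMS (-0.47, SE 0.12). Replication-dependent histones, whose transcripts mostly lack a poly(A) tail, had 7 of 16 members lower and 0 higher by either adjustment, that over all genes or that adjusted over the list alone (median -0.58; adjusted p = 5.92e-05; adjusted p = 0.0663 with an estimated correlation). H2AC6 fell by 1.23 (SE 0.16), H2BC4 by 0.99 (SE 0.18) and H2BC12 by 0.59 (SE 0.13) on the log2 scale, each uncertain because histone copies can share reads. The G2/M list lay at -0.32, the S phase list at -0.03 and the histone list at 0.07 in the libraries labelled U118-MG sgCon 2 and 3 relative to LN229 sgCon 2 and 3. With a share of 3.37% of U118-MG sgDDA1 taken out of those libraries these medians were -0.31, -0.01 and -0.01, and 62.5% of the histones had the sign of the LN229 response (37.5% before). DNA damage checkpoint genes had 7 lower and 1 higher of 25, the same counts adjusted over the list alone (adjusted p = 0.0237; adjusted p = 0.336 with an estimated correlation). HUS1, of the 9-1-1 clamp, fell by 0.67 (SE 0.08) and H2AX, the histone phosphorylated at breaks, dropped by 0.98 (SE 0.14), while ABRAXAS1 of the BRCA1-A complex rose by 0.63 (SE 0.14). Genes of the CRL4 complex had 8 lower and 3 higher of 27 (9 and 3 adjusted over the list alone; adjusted p = 0.0244; adjusted p = 0.193 with an estimated correlation). Among them were COPS3 (-0.52, SE 0.08), RBX1 (-0.45, SE 0.09) and DCAF1 (-0.34, SE 0.08). In the libraries labelled U118-MG sgCon 2 and 3 the checkpoint list lay at -0.17 and the CRL4 list at -0.04 relative to LN229 sgCon 2 and 3, against LN229 responses of -0.13 and -0.1 relative to sgCon 1. The sign was the same in the 2 comparisons for 48% and 59.3% of their members.

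Matrix and lineage genes rose in LN229 sgDDA1. Extracellular matrix and mesenchymal genes had 22 of 38 members higher and 1 lower (22 and 2 adjusted over the list alone; median 0.70; adjusted p = 1.01e-06; adjusted p = 0.15 with an estimated correlation). MMP2 rose from 3.45 ± 0.507 to 17.2 ± 0.883 CPM (2.32, SE 0.15), COL8A1 by 1.67 (SE 0.14) and COL5A1 by 1.04 (SE 0.09). Proneural and neural progenitor genes had 12 of 22 higher and 1 lower, the same counts adjusted over the list alone (median 0.56; adjusted p = 0.00216; adjusted p = 0.0486 with an estimated correlation). They included CD24 (2.30, SE 0.16) and SOX8 (1.60, SE 0.18). Of 12 markers of fibroblasts and pericytes 7 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.00963; adjusted p = 0.0958 with an estimated correlation). NOTCH3 rose from 27.8 ± 1.67 to 63.1 ± 5.40 CPM, whereas DCN and LUM reached 0.593 ± 0.0304 and 0.733 ± 0.0539 CPM. Antigen presentation genes had 10 higher and 2 lower of 22 (11 and 2 adjusted over the list alone; adjusted p = 0.00963; adjusted p = 0.336 with an estimated correlation). Among them were HLA-DPA1 (2.45, SE 0.16), HLA-DRB1 (1.91, SE 0.21, uncertain because related HLA genes share reads) and the transactivator NLRC5 (1.19, SE 0.14). These lists were also higher in the libraries labelled U118-MG sgCon 2 and 3 than in LN229 sgCon 2 and 3, at medians of 1.99 for matrix genes, 1.22 for proneural genes, 0.94 for fibroblast and pericyte markers and 0.48 for antigen presentation. Those libraries also carry genes specific to U118-MG sgDDA1, at a median of 3.37% of their level there. With that share of U118-MG sgDDA1 taken out, the medians were 1.00, 0.77, 0.90 and 0.35, and MMP2 went from 4.90 to 2.06.

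Smaller shifts in LN229 concerned metabolism. Autophagy and lysosome genes had 15 lower and 5 higher of 35, the same counts adjusted over the list alone (adjusted p = 0.00963; adjusted p = 0.336 with an estimated correlation). The receptor SQSTM1 fell by 0.77 (SE 0.11) and LAMP1 by 0.74 (SE 0.11), and TFEB, the transcription factor of lysosomal genes, rose by 1.06 (SE 0.17). Cholesterol and SREBP genes had 8 of 32 higher and 0 lower (10 and 1 adjusted over the list alone; adjusted p = 0.0499; adjusted p = 0.572 with an estimated correlation). The higher genes included INSIG1 (0.86, SE 0.09), FADS2 (1.00, SE 0.12) and ELOVL6 (0.92, SE 0.15). Cytosolic ribosomal protein genes had 7 of 38 higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.0445; adjusted p = 0.786 with an estimated correlation). RPL3 was at 0.44 (SE 0.11), RPL4 at 0.37 (SE 0.10) and RPL7 at 0.30 (SE 0.07). Nuclear genes of oxidative phosphorylation had 3 of 30 lower and 0 higher (1 and 0 adjusted over the list alone; adjusted p = 0.0253; adjusted p = 0.631 with an estimated correlation). These were SDHD (-0.50, SE 0.09), UQCRFS1 (-0.34, SE 0.11) and NDUFS3 (-0.39, SE 0.14). In the libraries labelled U118-MG sgCon 2 and 3, relative to LN229 sgCon 2 and 3, cholesterol genes lay at 0.18 and ribosomal proteins at 0.18, as far as in the LN229 response relative to sgCon 1 (0.15 and 0.17). Autophagy and lysosome genes lay at 0.03 and oxidative phosphorylation at 0.07 there, against responses of -0.2 and -0.14. With the share of 3.37% taken out, autophagy and lysosome genes lay at -0.04, with 82.4% of members of the sign of the LN229 response (67.6% before), oxidative phosphorylation at 0.08, cholesterol genes at 0.21 and ribosomal proteins at 0.20. Of the 15 lists called in LN229, the chaperone and proneural lists were also called with an estimated correlation. Both lost that call once the 6 libraries labelled U118-MG were left out (adjusted p = 0.152 and 0.0659).

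The second comparison was the same contrast in T98G. FDCSP, a small secreted peptide, dropped from 63.8 ± 5.06 to 1.14 ± 0.15 CPM (log2 fold change -5.81, SE 0.16, adjusted p = 3.4e-15, n = 3 per group), and AMTN, another secreted protein encoded near it on chromosome 4, by 4.98 (SE 0.25). Other large falls were SERPINB7 (-5.03, SE 0.41), the oxysterol receptor GPR183 (-3.87, SE 0.47), the adhesion receptor ADGRL4 (-3.72, SE 0.42) and FGFBP1 (-3.69, SE 0.50). Rises under the naming rule were led by the fibrinogen chain FGG (5.25, SE 0.71), CA9, a carbonic anhydrase induced by hypoxia (0.184 ± 0.0171 to 4.29 ± 0.370 CPM; 4.52, SE 0.41) and PI15 (3.89, SE 0.24). Further rises were RANBP3L (3.55, SE 0.41), the collagen gene COL3A1 (3.27, SE 0.32) and CBLN2, a synaptic organiser (6.10 ± 0.523 to 48.4 ± 1.73 CPM; 2.99, SE 0.16). In total 2857 genes were higher and 2545 lower, and at 2-fold or more 848 were higher and 794 lower. The 5402 calls became 9154 without the library labelled U118-MG sgCon 1 and 10013 without all 6 libraries labelled U118-MG.

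Glycolysis and hypoxia genes rose in T98G sgDDA1, with 25 of 32 higher and 0 lower (27 and 0 adjusted over the list alone) and a median of 0.62 (adjusted p = 2.31e-13; adjusted p = 0.11 with an estimated correlation). NDRG1 rose from 134 ± 8.88 to 644 ± 30 CPM (2.26, SE 0.11), the carbonic anhydrase CA12 from 40.4 ± 0.668 to 163 ± 6.65 CPM (2.01, SE 0.09) and the prolyl hydroxylase EGLN3 by 1.57 (SE 0.11). Replication-dependent histones had 12 of 16 members higher and 0 lower (13 and 0 adjusted over the list alone; median 1.90; adjusted p = 1.21e-12; adjusted p = 0.00373 with an estimated correlation). H4C8 was at 2.48 (SE 0.20), H2AC6 at 2.04 (SE 0.12) and H2BC12 at 1.88 (SE 0.14), each uncertain as above. All 13 mitochondrially encoded genes rose, also when adjusted over the list alone (median 0.50; adjusted p = 2.57e-09; adjusted p = 0.217 with an estimated correlation). The largest estimates included MT-ND4L (0.77, SE 0.09), MT-ND4 (0.74, SE 0.08) and MT-ND5 (0.62, SE 0.07). Mitochondrial genes took 5.59% to 5.68% of the counts in the 3 T98G sgDDA1 libraries and 4.2% to 4.53% in their controls.

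Chaperone genes fell in T98G as well, with 18 of 27 lower and 0 higher (19 and 0 adjusted over the list alone; median -0.50; adjusted p = 5.41e-12; adjusted p = 0.011 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, dropped from 1350 ± 44.9 to 823 ± 20.4 CPM (-0.72, SE 0.07), and DNAJB9 by 1.77 (SE 0.14). HSPA1B was lower by -0.83 (SE 0.10), with the reservation on its copy HSPA1A. NF-kB and inflammatory genes had 19 of 32 lower and 1 higher (21 and 1 adjusted over the list alone; median -1.17; adjusted p = 2.57e-09; adjusted p = 0.011 with an estimated correlation). BIRC3, an inhibitor of apoptosis, dropped from 770 ± 12.6 to 169 ± 2.96 CPM (-2.19, SE 0.12). The chemokine CCL5 fell from 817 ± 45.7 to 156 ± 13.0 CPM (-2.39, SE 0.13). The exception PTGS2, encoding cyclooxygenase 2, rose by 2.4 (SE 0.12). Interferon response genes had 23 of 40 higher and 6 lower (23 and 7 adjusted over the list alone; median 0.47; adjusted p = 0.000533; adjusted p = 0.188 with an estimated correlation). IFITM1 rose by 1.73 (SE 0.14), while the chemokines CXCL11 and CXCL10 fell by 2.68 (SE 0.15) and 1.53 (SE 0.13). Apoptosis regulators had 10 of 30 lower and 1 higher (12 and 2 adjusted over the list alone; adjusted p = 0.000707; adjusted p = 0.011 with an estimated correlation). The lower members included the death-promoting genes BMF (-1.64, SE 0.13) and PMAIP1 (-1.20, SE 0.11).

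Amino acid and mTORC1 genes, raised in LN229, were lower in T98G, with 12 of 30 down and 0 up (13 and 0 adjusted over the list alone; median -0.25; adjusted p = 0.00056; adjusted p = 0.374 with an estimated correlation). Lower members were STC2 (-0.91, SE 0.07), the amino acid transporter SLC7A5 (-0.90, SE 0.11) and MTHFD2 (-0.58, SE 0.07). Cholesterol and SREBP genes had 11 of 32 lower and 1 higher (16 and 1 adjusted over the list alone; adjusted p = 0.000371; adjusted p = 0.256 with an estimated correlation). SQLE was at -0.54 (SE 0.07), and the exception was the regulator SREBF1 at 0.88 (SE 0.10). Homologous recombination genes had 7 of 36 lower and 0 higher, also adjusted over the list alone (median -0.31; adjusted p = 0.00666; adjusted p = 0.514 with an estimated correlation). NBN, of the MRE11 complex, dropped from 135 ± 3.47 to 84.5 ± 1.38 CPM (-0.68, SE 0.13), RMI1 by 0.48 (SE 0.14) and RAD51C by 0.38 (SE 0.09). Replication licensing and S phase genes had 12 of 41 lower and 0 higher (14 and 0 adjusted over the list alone; adjusted p = 0.000701; adjusted p = 0.657 with an estimated correlation). CCNE1 was at -0.75 (SE 0.11), CDC6 at -0.54 (SE 0.07) and ORC1 at -0.50 (SE 0.10). Cytosolic ribosomal protein genes had 5 of 38 lower and 0 higher (3 and 0 adjusted over the list alone; adjusted p = 0.000501; adjusted p = 0.657 with an estimated correlation). Among these were RPS27A (-0.51, SE 0.11), RPS23 (-0.40, SE 0.10) and RPL6 (-0.28, SE 0.07). TGF-beta response genes had 10 of 23 lower and 3 higher (12 and 4 adjusted over the list alone; adjusted p = 0.0113; adjusted p = 0.256 with an estimated correlation). SMAD6 was lower (-0.83, SE 0.09), and IGFBP5 rose from 3030 ± 109 to 14100 ± 412 CPM (2.21, SE 0.09) and LTBP3 by 0.93 (SE 0.09). Of the 13 lists called in T98G, histones, chaperones, NF-kB genes and apoptosis regulators were also called with an estimated correlation. With the 6 libraries labelled U118-MG left out, apoptosis regulators lost that call (adjusted p = 0.173) and glycolysis and hypoxia genes gained it (adjusted p = 0.0314).

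**Figure D2:**
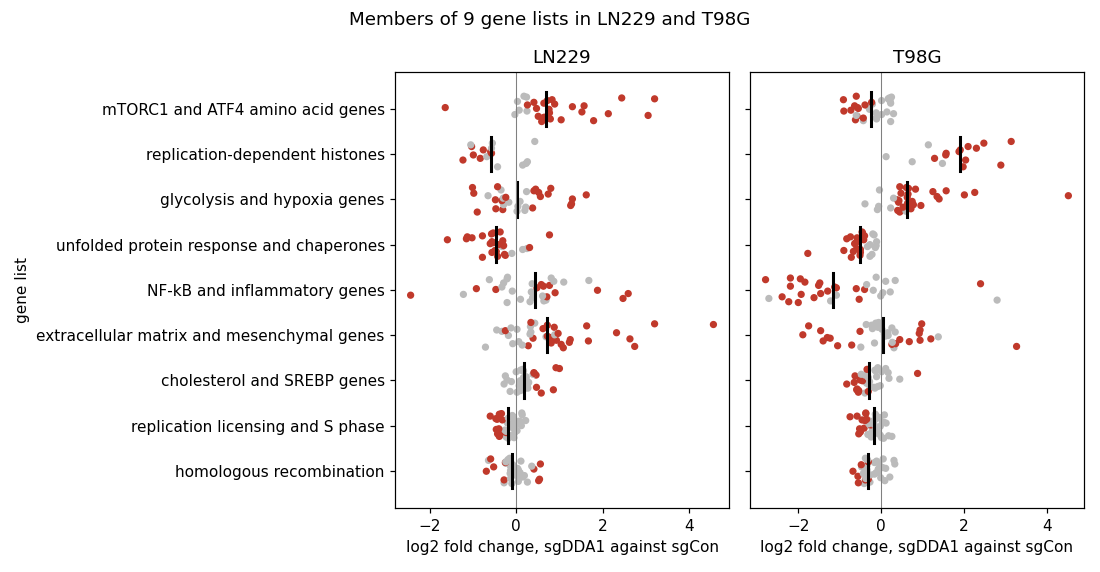
Log2 fold changes of sgDDA1 against sgCon (horizontal axis) for the members of the lists in LN229 and T98G, with points for genes, red for adjusted p under 0.05, grey otherwise, and a black bar for the list's median. Amino acid and mTORC1 genes have a median of 0.68 in LN229 and -0.25 in T98G, and histones -0.58 and 1.90, while chaperones lie at -0.46 and -0.50.

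The other lists of DNA repair that bear on the title were mostly not called. Homologous recombination was called lower in T98G and not in LN229, and the difference between the lines did not pass (adjusted p = 0.388; adjusted p = 0.754 with an estimated correlation). That difference passed without the 6 libraries labelled U118-MG (adjusted p = 0.00853; adjusted p = 0.396 with an estimated correlation). In LN229 homologous recombination had 4 higher and 5 lower of 36 (4 and 4 adjusted over the list alone; adjusted p = 0.242), with MCM9 at -0.59 (SE 0.11) and RAD51D at 0.54 (SE 0.10). Non-homologous end joining had 1 higher and 6 lower of 23 in LN229 (2 and 6 adjusted over the list alone; adjusted p = 0.109) and 1 higher and 2 lower in T98G, also adjusted over the list alone (adjusted p = 0.685). NHEJ1, a ligation factor, was lower in both, at -0.48 (SE 0.10) and -0.92 (SE 0.10), XRCC6, encoding Ku70, was lower in LN229 (-0.34, SE 0.09) and APTX in T98G (-0.35, SE 0.08). In T98G the DNA damage checkpoint list was not called (3 higher and 6 lower of 25 by both adjustments; adjusted p = 0.153), although CDC25A (-0.67, SE 0.11) and HUS1 (-0.52, SE 0.09) fell. It was called lower in T98G without the 6 libraries labelled U118-MG (adjusted p = 0.0398; adjusted p = 0.413 with an estimated correlation). The same held there for G2/M and mitosis (adjusted p = 0.0349 against 0.258; adjusted p = 0.663 with an estimated correlation) and nuclear genes of oxidative phosphorylation (adjusted p = 0.0199 against 0.0762; adjusted p = 0.564 with an estimated correlation). The CRL4 list was not called in T98G (1 higher and 5 lower of 27, 3 and 5 adjusted over the list alone; adjusted p = 0.456), where UBE2E2 was at -1.26 (SE 0.22) and DCAF8 at 0.35 (SE 0.08). Genes induced by p53 were called in neither line (adjusted p = 0.524 in LN229 and 0.254 in T98G). Their members SESN2 (0.76, SE 0.13) and CDKN1A (0.65, SE 0.13) rose in LN229, and in T98G CMBL rose by 0.90 (SE 0.12) and FAS fell by 0.77 (SE 0.11). Nucleotide excision repair (adjusted p = 0.35 and 0.982), mismatch and base excision repair (0.119 and 0.265) and Fanconi anaemia genes (0.524 and 0.456) were called in neither LN229 nor T98G.

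Whether the response itself differed between LN229 and T98G was tested directly. The difference passed for 4227 genes, with the response of T98G above that of LN229 in 1564 and below it in 2663 (8065 genes without the library labelled U118-MG sgCon 1, and 9044 without all 6 libraries labelled U118-MG). Of the lists, replication-dependent histones had a response higher in T98G (adjusted p = 7.86e-15; adjusted p = 0.00161 with an estimated correlation) and amino acid and mTORC1 genes a lower one (adjusted p = 7.86e-15; adjusted p = 0.0542 with an estimated correlation). Without the 6 libraries labelled U118-MG both passed with an estimated correlation (adjusted p = 0.0251 each). Of the 30 amino acid and mTORC1 genes the response was lower in T98G in 25 and higher in 1 (26 and 1 adjusted over the list alone). The chaperone list did not pass the test of a difference (adjusted p = 0.842), nor did replication and S phase (adjusted p = 0.842). FDCSP differed by -7.13 between the responses of T98G and LN229 (adjusted p = 1.37e-07), ANKRD1 by 3.74 (adjusted p = 5.83e-09) and DLX3, higher in LN229 and lower in T98G, by -5.56 (adjusted p = 2.81e-08). FDCSP was near a floor of 3 counts in LN229 (0.0254 CPM in sgCon and 0.0741 CPM in sgDDA1), so the size of its difference is uncertain.

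LN229 and T98G, which have their own control libraries, shared more calls than independent lists of these sizes would. They shared 1196 genes called higher against 549 for independent lists (odds ratio 3.72, Fisher's exact test p = 1.32e-197) and 555 called lower against 260 (odds ratio 2.87, p = 1.87e-75). A further 746 were called in opposite directions against 781 for independent lists. At 2-fold or more in both lines, 238 were shared higher against 78.2, 16 shared lower against 8.32, and 186 opposite against 82.1. Across 15755 genes the log2 fold changes of the 2 lines had a Pearson correlation of 0.08 and a Spearman correlation of 0.19, and genes are not independent replicates. COL3A1 (2.74 in LN229, 3.27 in T98G) and CA12 (1.62 and 2.01) were among the genes higher in both, and HUS1, NHEJ1 and CDC6 among those lower in both. Without the 6 libraries labelled U118-MG the shared numbers were 2286 higher against 1440 and 2100 lower against 1080.

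The libraries labelled U118-MG sgCon resembled LN229 rather than the libraries labelled U118-MG sgDDA1. On log2(CPM + 1) values over genes of at least 1 CPM, their correlation across genes was 0.91 to 0.965 with LN229 sgCon and 0.92 to 0.977 with LN229 sgDDA1, but 0.711 to 0.759 with U118-MG sgDDA1. The lines LN229 and T98G correlated at 0.772 to 0.778 in their controls, and the guides within LN229 and T98G at 0.98 to 0.985. Taking a protein-coding gene as on at 5 CPM or more in all 3 libraries and off below 0.3 CPM in all 3, 378 genes were on in U118-MG sgCon and off in U118-MG sgDDA1 and 25 the reverse, against 0 between the guides in LN229 and in T98G. A run of 13 neighbouring expressed genes on chromosome 9 (GRCh38, 20341665 to 27573866), from MLLT3 through MTAP and CDKN2A to C9orf72, was at 0.208 CPM or less in U118-MG sgDDA1. In U118-MG sgCon these genes were at 8.7 to 86.0 CPM, and in LN229 sgCon at 7.7 to 77.5 CPM. The run was chosen as the longest with means under 0.3 CPM in U118-MG sgDDA1, among 444 protein-coding genes of chromosome 9 on in LN229. That choice fixed low levels in U118-MG sgDDA1 and expression in LN229, and it did not use U118-MG sgCon. The library labelled U118-MG sgCon 1 also stood apart from the other 2 of its group, with a chi-square per gene of 173.29 and 174.14 against 3.7 to 21.86 for all other pairs within groups. CDKN2A, often described as deleted in LN229, was at 53.9 CPM in LN229 sgCon, so the label LN229 is itself open and all values given for LN229 are those of the libraries so labelled. The guide and the identity of the cells cannot be separated in the contrast of the groups labelled U118-MG.

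**Figure D3:**
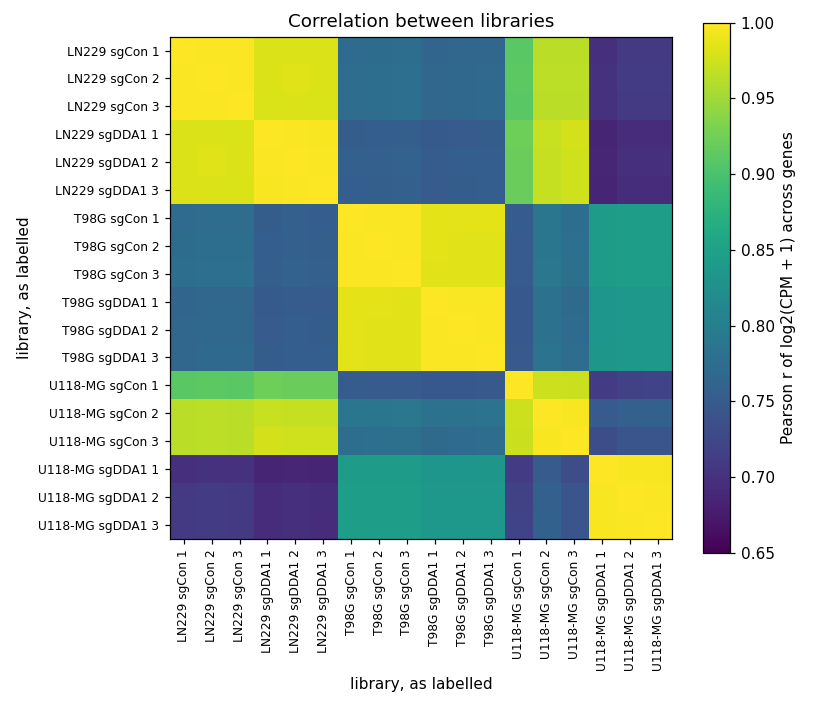
Pearson correlation across genes of log2(CPM + 1) between all pairs of the 18 libraries (both axes list the libraries by group, and the colour scale gives the correlation). The 3 libraries labelled U118-MG sgCon correlate at 0.91 to 0.977 with the LN229 libraries and at 0.711 to 0.759 with U118-MG sgDDA1.

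**Figure D4:**
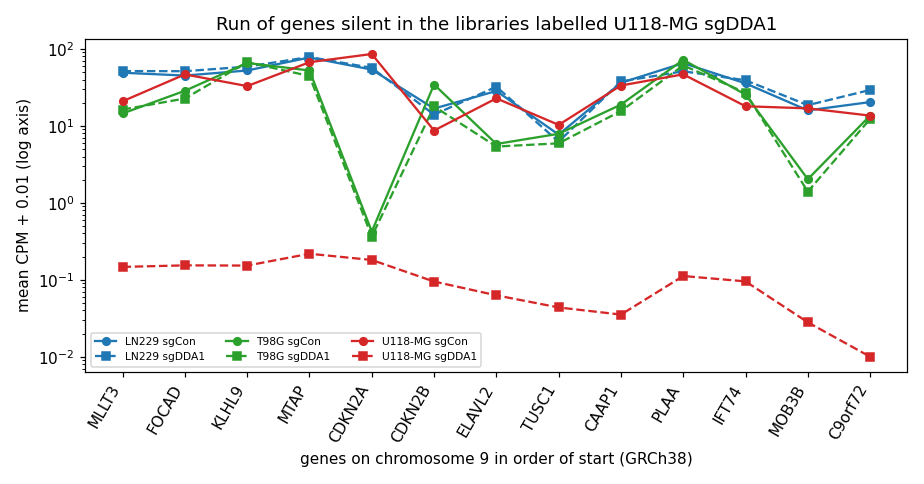
Mean CPM plus 0.01 per group (vertical log axis) of 13 expressed protein-coding genes in their order along chromosome 9 (horizontal axis). The genes lie at 0.208 CPM or below in U118-MG sgDDA1, where low levels were a condition of their choice, and at 8.7 to 86.0 CPM in U118-MG sgCon.

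As labelled, the contrast of U118-MG sgDDA1 against U118-MG sgCon called 8627 genes higher and 9002 lower, 5970 and 6404 of them by 2-fold or more. The collagenase MMP1 was at 2.85 ± 0.406 CPM in the libraries labelled sgCon and at 921 ± 86.8 CPM in those labelled sgDDA1 (n = 3 each; 8.34, SE 0.18, adjusted p = 9.55e-19). The urea transporter SLC14A1 was at 0.770 ± 0.240 and 179 ± 23.6 CPM, and TNFRSF11B, encoding osteoprotegerin, at 0.920 ± 0.377 and 151 ± 77.4 CPM. BCL2A1, CLCA2 and GABRA4 were at or near the floor in sgCon and at 18.8, 14.1 and 2.47 CPM in sgDDA1. GPR27, HEYL, HOXA7, C9orf72, MYT1 and ECEL1 had 0 counts in all 3 sgDDA1 libraries and 11.5 to 19.7 CPM in sgCon, so against a floor of 3 counts per library they were at least 244-fold (GPR27) to at least 143-fold (ECEL1) lower. Lists called higher with the preset correlation included mesenchymal glioma state (23 of 24 higher and 1 lower, also adjusted over the list alone, adjusted p = 2.74e-09; adjusted p = 0.126 with an estimated correlation), with CAV1 at 4.81 (SE 0.12). Extracellular matrix was higher too (32 of 38 higher and 4 lower, adjusted p = 4.3e-09; adjusted p = 0.126 with an estimated correlation), with fibronectin, FN1, at 767 ± 121 and 35500 ± 2310 CPM. Replication and S phase genes were lower (34 of 41 lower and 1 higher, adjusted p = 5.97e-07; adjusted p = 0.389 with an estimated correlation), as were ribosomal protein genes (33 of 38, adjusted p = 7.33e-05) and cholesterol genes (22 of 32, adjusted p = 0.00268). NF-kB genes (adjusted p = 2.55e-06), COP1-DET1 substrates and ETS target genes (4.71e-05), interferon response and autophagy genes (7.33e-05 each), antigen presentation (8.86e-05), glycolysis and hypoxia (0.000104), TGF-beta response (0.000631) and histones (0.0122) were higher. None of these 13 lists was called with an estimated correlation, where the lowest adjusted p was 0.126.

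Across the 3 lines, as the deposited comparison is named, a fit with cell line as an additive term called 3026 genes higher and 2066 lower in sgDDA1. This total of 5092 was 212 with no cell line term, 1020 with a replicate block and 13461 for the mean of the per-line contrasts. The genes named here were chosen on all 18 libraries, so they carry the contrast of the groups labelled U118-MG. HGF, hepatocyte growth factor, had a log2 fold change of 4.82 (SE 0.69, adjusted p = 0.000264), with 2.52 in LN229, 2.67 in T98G and 6.50 in the libraries labelled U118-MG. DSCAM (5.24, SE 0.75), the olfactory receptor OR2M4 (5.03, SE 0.35), TREM1 (4.17, SE 0.63), CLCA2 (4.03, SE 1.00) and HSPB7 (3.87, SE 0.58) were also among the largest rises. The largest falls were ANKRD1 (-3.07, SE 0.51), EMILIN2 (-2.72, SE 0.89), COL6A5 (-2.63, SE 0.79), ACTL8 (-2.28, SE 0.49), C3orf14 (-2.14, SE 0.56) and ABLIM1 (-2.06, SE 0.67). The DDA1 level, across the 3 lines, did not pass (-0.21, SE 0.09, adjusted p = 0.105). With LN229 and T98G alone it did (-0.36, adjusted p = 0.000457). LN229 and T98G alone gave 4734 genes higher and 3693 lower.

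Replication and S phase genes led the lists across lines, with 20 of 41 lower and 0 higher (33 and 0 adjusted over the list alone; median -0.47; adjusted p = 9.75e-11; adjusted p = 0.445 with an estimated correlation). CDC6 (-0.62, SE 0.07), ORC1 (-0.74, SE 0.13) and the reductase subunit RRM2 (-0.54, SE 0.09) were lower in each line. Glycolysis and hypoxia genes had 16 of 32 higher and 0 lower (17 and 0 adjusted over the list alone; adjusted p = 4.24e-07; adjusted p = 0.445 with an estimated correlation), led by the enolase ENO2 (1.47, SE 0.11), CA12 (2.35, SE 0.21) and PFKFB4 (1.22, SE 0.12). CA12 was also higher, by 2.81, in the libraries labelled U118-MG sgCon 2 and 3 than in LN229 sgCon 2 and 3. Chaperones had 8 of 27 lower and 1 higher (11 and 1 adjusted over the list alone; adjusted p = 0.000282; adjusted p = 0.445 with an estimated correlation), and in LN229 and T98G alone this list was called also with an estimated correlation (adjusted p = 0.0015). HYOU1 (-0.60, SE 0.06) and SDF2L1 (-0.92, SE 0.14), both of the endoplasmic reticulum, fell. Mismatch and base excision repair had 9 lower and 3 higher of 29 (11 and 3 adjusted over the list alone; adjusted p = 0.0408; adjusted p = 0.445 with an estimated correlation, and adjusted p = 0.0712 in LN229 and T98G alone), including the glycosylases UNG (-0.59, SE 0.10) and TDG (-0.72, SE 0.15). Extracellular matrix (19 of 38 higher and 1 lower, adjusted p = 3.27e-07), interferon response (14 of 40 higher and 1 lower, adjusted p = 1.95e-05) and mitochondrially encoded genes (3 of 13 higher, adjusted p = 0.0132) were called higher, with TIMP3 (1.04, SE 0.11), IFI6 (1.07, SE 0.15) and MT-CYB (0.42, SE 0.10) as examples. With an estimated correlation their adjusted p-values were 0.445, 0.445 and 0.58. Homologous recombination (9 of 36 lower and 1 higher, adjusted p = 0.0191) and nuclear genes of oxidative phosphorylation (6 of 30 lower, adjusted p = 0.00411) were called lower, with RAD51C at -0.85 (SE 0.20) and NDUFS3 at -0.58 (SE 0.13), and with an estimated correlation both had an adjusted p of 0.445. With the preset correlation these 5 lists kept their call in LN229 and T98G alone. In the per-line comparisons on all 18 libraries, matrix and oxidative phosphorylation were called in LN229 and not in T98G. The others were called in T98G and not in LN229. NF-kB genes were called higher (adjusted p = 0.0408; adjusted p = 0.674 with an estimated correlation) but lower in LN229 and T98G alone (adjusted p = 0.011; adjusted p = 0.551 with an estimated correlation). None of the 16 lists called on all libraries was called with an estimated correlation, and mesenchymal glioma state (adjusted p = 1.2e-06), antigen presentation (0.000474), COP1-DET1 and ETS targets (0.000798), histones (0.00286), ribosomal proteins (0.000123) and cholesterol genes (0.00813) lost their call in LN229 and T98G alone. Lists called only in LN229 and T98G alone were G2/M and mitosis (lower, adjusted p = 1.6e-06; adjusted p = 0.44 with an estimated correlation), proneural genes (higher, 0.00288; 0.0938), DNA damage checkpoint (lower, 0.00676; 0.0938) and autophagy and lysosome genes (lower, 0.0125; 0.258).

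The test of whether the response differed among the 3 lines passed for 16728 genes, and for 9044 between LN229 and T98G once the libraries labelled U118-MG were left out. SEPTIN6, SULF2, IGF2BP1, SEPTIN3, LTBP1 and LYN had the smallest p-values (adjusted p = 1.4e-18 to 5.59e-18), each with its largest change in the groups labelled U118-MG. IGF2BP1, an RNA-binding protein, was at -8.40 there, and at -0.35 in LN229 and -0.41 in T98G.

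The authors' deposited table of sgCon and sgDDA1 lists 36 genes higher and 6 lower, with log2 fold changes of LN229. It held the genes that passed a DESeq2 adjusted p of 0.05 with at least a 2-fold change in the same direction in all 3 lines, 36 of 36 and 6 of 6 in a separate fit per line. In the authors' deposited table the smallest adjusted p-values belonged to LRP1 (log2 fold change 1.53), a large endocytic receptor, the sulfatase SULF1 (1.29), CA12 (1.55), SPEG (1.21) and NMRK1 (1.31) among the higher genes. Among the lower genes of the authors' deposited table they belonged to EMILIN2 (-1.02), a transcript without a symbol, ENSG00000261924 (-2.83), PRR22 (-1.09), ZSCAN12P1 (-1.03) and PTAFR (-1.40). In the edgeR fits 35 of the 36 higher genes were called higher in LN229 and 36 in T98G, and all 6 lower genes were called lower in both. In the DESeq2 fits LN229 and T98G shared 199 higher and 18 lower genes at this threshold, of which 37.7 and 3.82 would pass in the libraries labelled U118-MG if that contrast were independent of the other lines.

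Lists of cell types that a culture could contain were examined in LN229 and T98G. Apart from the fibroblast and pericyte markers in LN229, none was called in either line. Adjusted p-values in LN229 and T98G were 0.21 and 0.982 for astrocyte markers, 0.982 and 0.982 for oligodendrocyte markers, 0.597 and 0.982 for neuron markers, and 0.982 and 0.102 for microglia and macrophage markers. They were 0.624 and 0.949 for endothelial markers and 0.35 and 0.871 for epithelial markers. Immediate early and serum response genes were also called in neither (0.686 and 0.0803), nor were mesenchymal glioma state genes (0.0695 and 0.982) or COP1-DET1 substrates and ETS target genes (0.0695 and 0.515). The mesenchymal glioma state list was called higher in LN229 without the 6 libraries labelled U118-MG (adjusted p = 0.0451; adjusted p = 0.265 with an estimated correlation). Median, mean and test differed in sign for some lists that were not called. In LN229 the medians of microglia and endothelial markers were -0.08 and -0.03 and the test pointed up, and in T98G the median of mesenchymal glioma state genes was -0.23 and the mean 0.12. In T98G the p53 list had a median of -0.08 and a mean of 0.05, and COP1-DET1 and ETS targets -0.04 and 0.04. Nucleotide excision repair had negative medians and positive means in both lines (-0.07 and 0.01 in LN229, -0.05 and 0.03 in T98G), epithelial markers in T98G had a median of -0.14 with a test pointing up, and in LN229 the Fanconi anaemia list had a median of 0.02 with a test pointing down.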

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

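Chosen only after the result was seen were the 3 tests on the identity of the libraries labelled U118-MG, the test of GC content and length in the library labelled U118-MG sgCon 1, and the comparison of LN229 rises with the libraries labelled U118-MG sgCon. The tests of library size, of GC content and length in LN229, of the share of 2 cultures and of the splits were written before.

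A tested difference of response between cell lines marked every result of this part. The response differed among the 3 lines for 16728 genes, between T98G and LN229 for 4227, between U118-MG and LN229 for 14950 and between U118-MG and T98G for 14679. Counts and p-values for a contrast of the groups labelled U118-MG carry the identity of their cells, which cannot be separated from the guide there. Between T98G and LN229 the number was 9044 without those libraries. The smallest adjusted p-values (edgeR) among the 3 lines were 1.4e-18 for SEPTIN6, 1.4e-18 for SULF2, 2.15e-18 for IGF2BP1, 5.32e-18 for SEPTIN3, 5.59e-18 for LTBP1 and 5.59e-18 for LYN.

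On the log2 scale the response of T98G minus that of LN229 was -2.65 for CACNA1I, -3.03 for HES2, -4.07 for FUT1, -7.49 for USH1G and -5.56 for DLX3, genes that rose in LN229. It was 3.74 for ANKRD1, 2.47 for DNAH17, 1.35 for FAM71F2 and 5.26 for MGAM, genes that fell in LN229. Among genes that rose in T98G it was 4.44 for FGG, 5.17 for CA9, 3.03 for PI15, 2.39 for RANBP3L and 3.96 for CBLN2. Among genes that fell in T98G it was -7.13 for FDCSP, -5.64 for SERPINB7, -4.32 for AMTN, -3.26 for GPR183, -3.22 for ADGRL4 and -4.20 for FGFBP1. Some of these differences rest on a line where the gene was near or under a floor of 3 counts, so their sizes are uncertain. In T98G USH1G was at 0.0395 CPM in sgCon and 0 CPM in sgDDA1, and MGAM at 0.00644 and 0.106 CPM. In LN229 FGG, CA9, CBLN2, FDCSP, SERPINB7 and AMTN were at 0.0127 to 0.0442 CPM in sgCon and 0.0107 to 0.0808 CPM in sgDDA1.

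Of the gene lists, the response was higher in T98G than in LN229 for histones (adjusted p = 7.86e-15), glycolysis and hypoxia (3.98e-09), mitochondrially encoded genes (2.43e-05) and G2/M and mitosis (0.00743). It was lower in T98G for amino acid and mTORC1 genes (7.86e-15), NF-kB genes (1.5e-06), extracellular matrix (1.5e-06), cholesterol genes (1.31e-05), ribosomal proteins (2.43e-05), antigen presentation (0.000538), fibroblast and pericyte markers (0.00327), TGF-beta response (0.014) and apoptosis regulators (0.0385). With an estimated correlation only histones passed (adjusted p = 0.00161). Without the 6 libraries labelled U118-MG histones and amino acid and mTORC1 genes passed (adjusted p = 0.0251 each).

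The guides were relabelled within each line in 100 splits, with the real labels as 1 of them. For the difference between T98G and LN229, 1 of 100 splits, the real one, reached the real number (4227, highest other 1924). The same held for the comparison across lines (5092, highest other 1441). It also held for the difference among the 3 lines (16728, highest other 15264), although another split called nearly as many genes. Within LN229, T98G and the libraries labelled U118-MG, 1 of 10 splits each, again the real one, reached the real number. The real numbers were 7185, 5402 and 17629 (highest other 1, 1 and 0), and 10 splits are too few for a share under 0.05.

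The libraries labelled U118-MG sgCon may hold mostly RNA of the culture labelled LN229. Of 280 genes on in LN229 and off in U118-MG sgDDA1, 93.2% were on in all 3 of them and 0 were off in all 3. The share asked for at first was 95%, which was missed, and the criterion that decided was set after this value was seen. A minor share of U118-MG cells also fits, since 48 genes specific to U118-MG sgDDA1 lay at a median of 3.37% of their level there. The lowest correlation of 0.91 with LN229 sgCon restates the resemblance, so it cannot decide on an effect of the guide on a single line. Such an effect is not favoured by the 378 genes on in U118-MG sgCon and off in U118-MG sgDDA1. There were 25 the reverse, against 0 between the guides in LN229 and in T98G. Which of the labels is wrong was not tested, and the deposited counts give no cell line typing.

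The library labelled U118-MG sgCon 1 could differ from the other 2 of its group in the quality of the RNA recovered. GC content and gene length explained 69.9% of the variance across 10074 genes of its log2 ratio to them, against 2.28% between sgCon 2 and 3. Another share of the 2 cultures is not favoured, since genes specific to each moved apart by 0.11 after that trend was removed. No biological explanation was tested.

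The rise of low-abundance genes in LN229 sgDDA1 might come from the DDA1 guide or from a difference between cultures of a line that does not need it. With totals made equal 90.6% of the 2-fold calls were still higher, and with the trend in GC content and length removed the gap between genes of 1 to 10 and over 100 CPM was 0.43, so neither accounts for it. Of 320 risers off in U118-MG sgDDA1, 77.2% were also 2-fold higher in the libraries labelled U118-MG sgCon 2 and 3, whose guide was not tested, than in LN229 sgCon 2 and 3, against 13.6% of 948 other genes. If the guide label of those libraries is right this fits a difference between cultures, and an effect of the guide remains open.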

How the results depend on the processing

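All 263 named results kept direction and side of the threshold under DESeq2, DESeq2 size factors, a robust prior and halved counts, 262 with no filter and 240 of 241 with a filter of 5 CPM in 3 libraries. Without the 6 libraries labelled U118-MG 192 did and 9 lost their call, with no cell line term 7 did and 60 lost it, and under a replicate block 234 did and 29 lost it. Leaving out single libraries kept 4684 and ended 50. Halved counts, the fits without the libraries labelled U118-MG and the T98G minus LN229 counts were added after the data were seen, and unless a setting's construction shows it the cause was not tested.

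Each line alone gave 11923 genes in LN229 and 10215 in T98G, with the DDA1 level, T98G, at -0.19 (adjusted p = 0.000623) and DDA1 at -0.05 in the libraries labelled U118-MG (adjusted p = 0.802), a reversed sign. Without the 6 libraries labelled U118-MG there were 11632 genes in LN229, 10013 in T98G, 8427 across lines, and 9044 for the difference between lines, which is then also that between T98G and LN229. DDA1 was then at -0.20 in T98G and -0.36 across lines, the overlap of calls between lines, LN229 and T98G, was 4386, and NF-kB genes turned to lower across lines (adjusted p = 0.011, and 0.551 with an estimated correlation). At 2-fold or more, sgDDA1 against sgCon in LN229 gave 2508 genes, sgDDA1 against sgCon in T98G 1642, with 1616 across lines, 254 shared by LN229 and T98G and 56 by all 3 lines, since fewer genes reach 2-fold. The filter of 5 CPM left fewer genes to test, with 11263 called in U118-MG and 11139 for the difference between lines. No cell line term gave 212 across lines and 10 genes of the authors' deposited table. The mean of the per-line contrasts, which leaves differences between lines out of the residual, gave 13461, and the DDA1 level, across lines, was -0.21 (adjusted p = 0.00514).

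With an estimated correlation 2 lists were called in LN229, 4 in T98G, 0 in U118-MG and 0 across lines. Without the libraries labelled U118-MG as well, 0 were called in LN229, 4 in T98G (glycolysis and hypoxia in place of apoptosis regulators) and 1 across lines. The fry test, which asks whether a list changes at all and not whether it stands out from other genes, called 23 in LN229 and 30 in U118-MG. Under fry 49 of the 57 calls of lists in the main fit stayed and 8 were lost. Lost were S phase and ribosomal proteins in LN229 and T98G and oxidative phosphorylation in LN229. Across lines ribosomal proteins, cholesterol genes and NF-kB genes lost theirs.

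Leaving out single libraries gave 5267 to 10898 genes in LN229, 3886 to 9154 in T98G, 17087 to 18499 in U118-MG, 3497 to 5040 across lines, 16171 to 18318 for the difference between lines and 3365 to 8065 for T98G minus LN229. The library labelled U118-MG sgCon 1 gave the highest of these when left out, in all but the comparison across lines. DDA1 ranged from -0.55 to -0.49 in LN229, -0.24 to -0.16 in T98G, -0.02 to 0.25 in U118-MG and -0.26 to -0.18 across lines. Lists called ranged from 13 to 17 in LN229, 13 to 14 in T98G and 14 to 18 across lines, and stayed at 13 in U118-MG. Shared calls ranged from 1242 to 3756 for LN229 and T98G and from 529 to 1719 for all 3 lines, and genes of the authors' deposited table from 40 to 42 in LN229, 37 to 42 in T98G and 41 to 42 across lines, with 42 in U118-MG.

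A replicate block gave 1020 genes across lines, 6525 in LN229, 4766 in T98G and 17241 in U118-MG. Correlations of libraries with the same number ran from -0.08 to 0.12. In LN229 those with the same number (0.05 to 0.12) lay above those with different numbers (-0.11 to 0.02), so a weak pairing there is not excluded. In T98G and the libraries labelled U118-MG they overlapped. Depth limits genes near 3 counts.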

Other observations

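The genes of this paragraph were chosen after their values were seen, as changed alike in LN229 and T98G. The collagen gene COL3A1 (2.74 in LN229 and 3.27 in T98G), the complement inhibitor SERPING1 (2.43 and 2.98), PPFIA4 (2.12 and 2.49) and the hormone gene STC1 (1.77 and 1.98) rose in both. So did the glycolytic enzymes ENO2 (1.30 and 1.40) and PFKFB4 (1.26 and 0.96). HSPA5, the main chaperone of the endoplasmic reticulum, fell by 0.78 and 0.72, and NBN, which acts in the sensing of DNA breaks, by 0.69 and 0.68. NBN was at 47.7 CPM in the libraries labelled U118-MG sgCon and at 108 CPM in U118-MG sgDDA1.

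Other genes, likewise picked after their values were seen, moved in opposite directions in LN229 and T98G. The death-promoting gene PMAIP1 was at 0.71 in LN229 and -1.20 in T98G, and BMF at 1.10 and -1.64. STC2 was at 0.83 and -0.91, and the mitochondrial folate enzyme MTHFD2 at 0.51 and -0.58, each with an edgeR adjusted p under 0.05 in each line.

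Further tests on the rise of low-abundance genes in LN229 sgDDA1 were written before their values were seen. For an even background of DNA or unspecific reads, 1566 genes near 0 rose by a mean of 0.00076 FPKM. That is 0.2% of the median rise of 0.388 FPKM of genes called higher at 2-fold. These genes were chosen with a mean under 0.01 FPKM in the LN229 libraries themselves. That choice capped their rise, so this test cannot decide. For carry-over from the libraries labelled U118-MG sgDDA1, their share by marker genes was 0.0047%. Of the genes called higher at 2-fold, 0% rose within 2 times that share. The marker genes had to be below 0.3 CPM in every LN229 library, LN229 sgDDA1 included. This limits the share they can show, so the test cannot decide either.

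CDKN2A was at 53.9 CPM in LN229 sgCon, 0.414 CPM in T98G sgCon, 86.0 CPM in the libraries labelled U118-MG sgCon and 0.171 CPM in U118-MG sgDDA1. The identity of the libraries labelled LN229 was not tested.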
